A study of Homo sapiens with 12 samples.

How the data were processed

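Total RNA of 12 HEK293 cultures was labelled with biotin and hybridized to single-colour oligonucleotide arrays of 22283 probe sets, per the labels. The deposited values are MAS5 signals, that is intensity on a linear scale with 1 value per probe set and array; MAS5 is named per the submitters' processing notes, and its version, detection calls and scan dates are not given in the sources used here. The 2% trimmed mean lay between 1000.33 and 1000.4 on every array, so the deposited intensity values had already been scaled to a common level by the authors, and no further scaling was applied. The labels state that RNA showed no sign of degradation and that the actin 3'/5' ratios were below a limit, which the deposited values show as 1.19 to 1.95. All 12 columns of the table belong to samples of this series. Groups and clone numbers were taken from the sample titles. For the induced A263insGG clone 6 array another label names clone 5, and the title was used.

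Probe sets were named through the platform annotation given with the data, with symbols updated by Entrez identifier from a RefSeq gene table of GRCh38.p14. That table served for names only, and no coordinates are given because the annotation names no genome build. There were 19065 probe sets with 1 symbol, 1043 with several and 2107 not listed in the annotation; 19053 symbols matched by Entrez identifier. No gene was named from a probe set with several symbols.

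The 68 control probe sets were set aside, and log2(signal + 57.3) was used for the other 22215. The offset is the 20th percentile of all values, and it makes the changes of dim transcripts smaller than on the plain scale. A probe set was kept if its mean signal reached 187.8, the 40th percentile, in at least 1 group, which left 15233. One linear model with a mean for each of 6 groups was fitted over all arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with eBayes using an intensity trend and robust variances, 6 residual and 9.71 prior degrees of freedom. Tests are two-sided with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The contrasts were induced minus uninduced in each line, differences between these contrasts, and a moderated F test over the 3 uninduced groups. No arrays are shared between the contrasts of different lines, but the estimate of spread is. Clones are separate cell lines from 1 parental line. The p-values rest on the spread between the 2 arrays of a group, pooled over the 6 groups. This spread holds differences between clones together with differences between single arrays.

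The labels' clone numbers pair an induced with an uninduced array of the same clone. Deviations of the paired arrays from their group means correlated with 0.0702 for HNF1b, -0.226 for HNF1a and 0.166 for A263insGG across probe sets. The fit with the clone as a block was run as an alternative.

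Gene lists (HNF1 transgenes, HNF1 targets, apical peptidases, plasma proteins of hepatocytes, liver and endoderm transcription factors, kidney tubule, cystic kidney and cilium, epithelial junction, extracellular matrix and mesenchymal genes, conjugation and drug transport, cholesterol synthesis, ATF4 and unfolded protein response, oxidative phosphorylation, proliferation, p53 targets, interferon response, immediate early genes, glycolysis and hypoxia, neuronal, hematopoietic and endothelial, and housekeeping genes) were tested with camera at a preset correlation of 0.01, with 1 probe set per gene. Of 21 lists, 19 had the minimum of 5 measured members; the list of transgenes had 0. Sets ranked in the HNF1b lines were tested with fry, which asks whether the genes of a set move one way and does not compare them with other genes.

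The model, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the largest changes among genes that pass or, if fewer than 5 genes pass, the 10 of smallest p in an induction contrast and the 5 of smallest p in a difference, besides the 8 of smallest p between uninduced lines, up to 4 members of each list, and DPP4, ALB, FGB, SERPINA1, HNF4A, PKHD1 and UMOD. The values of TKTL1, PCBD1, GLA, LGR5 and SPP1 outside the comparisons for which that rule names them, other probe sets of named genes, and which of the up to 4 members of a list are printed, were chosen after their values were seen. Because 0 genes were called for HNF1b, 50 ranked genes per direction, which had been named for comparison, took the place of the called genes.

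Alternatives covered quantile normalization, median scaling, the offset, the filter, the variance model, array weights, 1 probe set per gene, the clone as a block, the arrays in the fit, a rule of at least 2-fold in both clones, and leaving out each array. The fit was tested on simulated data with 200 changed probe sets among 15233, drawn with the real means, the moderated spreads of the fit and normally distributed errors. With HNF1b it recovered 45 of 67 probe sets changed by 1 on the log2 scale, 64 of 69 changed by 2 and 64 of 64 changed by 3, with 8 false calls. With HNF1a it recovered 42 of 64, 65 of 68 and 67 of 68, with 10 false calls, and with A263insGG 43 of 68, 63 of 66 and 65 of 66, with 6. These rates hold for 200 changed probe sets, because the Benjamini-Hochberg cut is stricter where fewer change. They do not show what the fit can find where few change. In the real data TKTL1, at 2.33 with HNF1b, had a limma adjusted p of 0.382. Spike-in controls were averaged as log2 signals over their probe sets and compared with exact permutation tests. Plots were drawn with matplotlib 3.10.9.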

Results

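Transcript levels were measured in HEK293 cells, an established human embryonic kidney cell line, that carried 1 of 3 tetracycline-inducible transgenes. These were HNF1b (hepatocyte nuclear factor 1 beta), HNF1a (the related factor hepatocyte nuclear factor 1 alpha) and the HNF1b mutant that the labels name A263insGG. Both wild-type proteins are homeodomain transcription factors of liver, kidney, gut and pancreatic islets. Each transgene was studied in 2 clones, clones 1 and 2 for HNF1b, 1 and 4 for HNF1a, and 5 and 6 for A263insGG. Every clone was profiled once after 24 h with 1000 ng/ml tetracycline (induced) and once after vehicle (uninduced), which gave 12 single-colour oligonucleotide arrays in 6 groups of 2. The median signal of an array lay between 277.5 and 355 intensity units, and the number of arrays limits the precision of all comparisons. No probe set is assigned to HNF1A or HNF1B in the annotation used here, so transgene levels were not analysed here and the induction labels were not checked against them.

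The first comparison asked which transcripts differ when HNF1b is switched on. TKTL1, a relative of the pentose phosphate enzyme transketolase, had a signal of 336 ± 21.1 (SD, n = 2) with induction and 21.2 ± 1.91 without, a log2 change of 2.33 (SE 0.43). PCBD1, a pterin dehydratase that also binds HNF1 proteins as a dimerization cofactor, went from 1738 ± 24.6 to 3079 ± 439, a log2 change of 0.80 (SE 0.14). SPP1, the secreted matrix phosphoprotein osteopontin, measured 25.6 ± 21.4 without and 308 ± 62.4 with induction, a log2 change of 2.15 (SE 0.52). LGR5, a receptor for R-spondins and marker of epithelial stem cells, measured 1940 ± 125 without and 1124 ± 4.1 with HNF1b, a log2 change of -0.76 (SE 0.14). All 4 had the same sign in both clones, but none passed the test over all probe sets: the limma adjusted p was 0.382 for TKTL1, PCBD1 and LGR5 and 0.999 for SPP1.

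The other genes of smallest p with HNF1b did not pass either. The lysosomal enzyme GLA (alpha-galactosidase A) had a log2 change of 0.47 (SE 0.11) and PCOTH of -1.39 (SE 0.33). DDRGK1, a component of protein ufmylation at the endoplasmic reticulum, had a change of 0.67 (SE 0.15). The probe sets of AHCYL1, a binding partner of the inositol trisphosphate receptor, XRCC4, a DNA end-joining factor, and SSR1, a subunit of the translocon-associated complex, gave 0.89, 0.89 and 0.66. Other probe sets of these genes had smaller or opposite values, -0.03, -0.04 and 0.22 for AHCYL1, -0.08 and 0.45 for XRCC4, and 0.05, -0.07 and -0.13 for SSR1. Before induction the HNF1b lines read lower than the HNF1a and A263insGG lines for AHCYL1 (625 against 973 and 932). The same held for XRCC4 (615 against 822 and 943) and DDRGK1 (1749 against 2942 and 2468). SSR1 measured 5060 against 5051 and 7944. A second probe set each of TKTL1 and LGR5 gave 1.66 and -0.68. DPP4, an apical membrane peptidase, measured 127 ± 9.48 without and 288 ± 84.6 with HNF1b, a log2 change of 0.88 (SE 0.37, limma adjusted p 0.999). SERPINA1, the plasma protease inhibitor alpha-1-antitrypsin, measured 92.2 ± 53.2 and 96 ± 13.2, a change of 0.08 (SE 0.53). ALB and FGB lay below the signal filter in all groups, and HNF4A, PKHD1 and UMOD have no probe set in the annotation used here.

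Among 15233 probe sets, limma called 0 for HNF1b at an adjusted p under 0.05, and 517 had an unadjusted p under 0.05 (335 higher, 182 lower) where 762 are due by chance. Without the intensity trend and robust variance 1 was called, TKTL1 (adjusted p 0.00275), and without the clone 2 induced array 1 other, lower, was called.

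**Figure D1:**
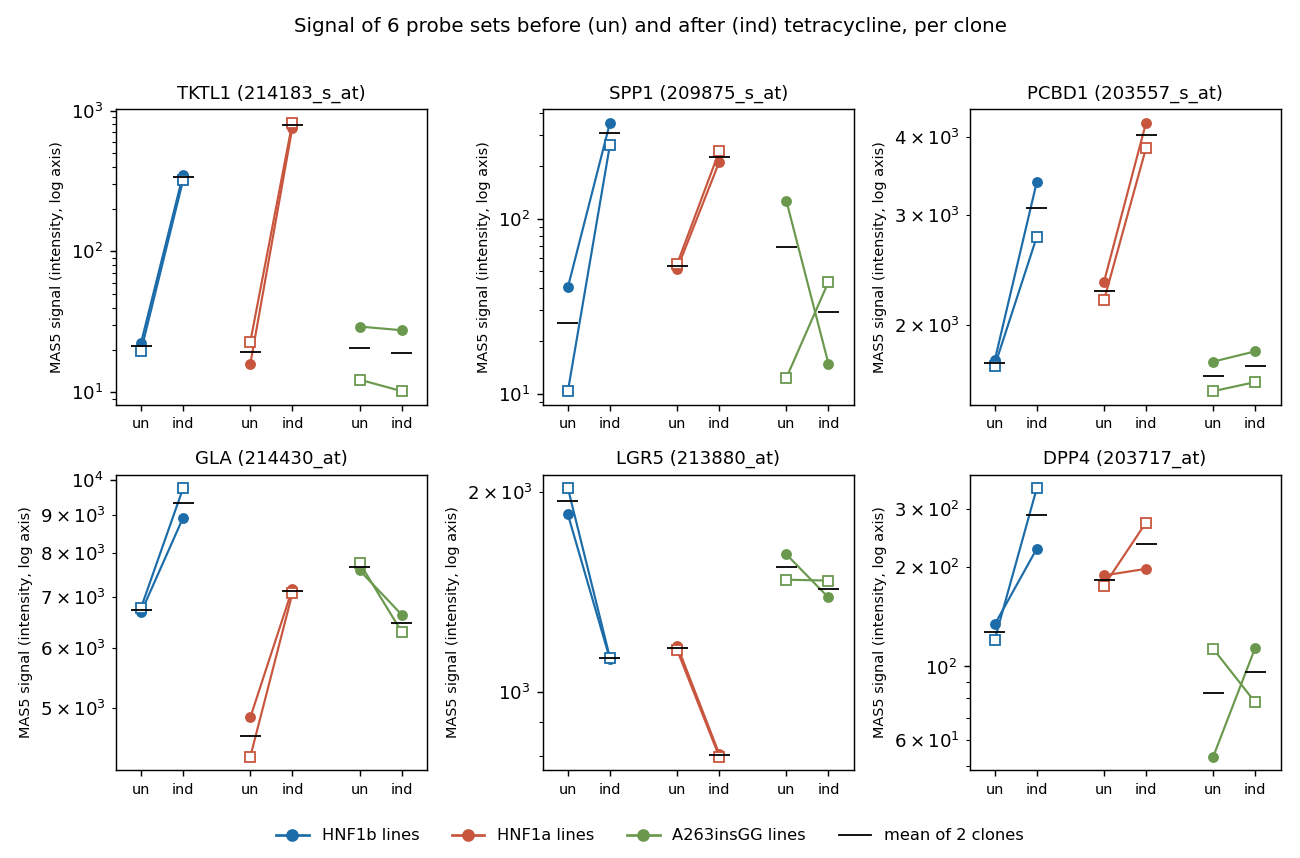
Signal of 6 probe sets (intensity, log axis) on each array, uninduced (un) and induced (ind), with lines joining the 2 arrays of a clone, filled circles for the clone of lower number, open squares for the other, and black bars at the mean of both. TKTL1 lies at 336 and 788 on average in the induced HNF1b and HNF1a lines and at 18.9 in the induced A263insGG lines.

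The gene groups fixed beforehand were compared as lists with HNF1b induction, and camera called 0 of the 19 lists that had at least 5 measured members (adjusted p 0.551 to 0.904, and 0.937 for all of them with an estimated correlation). The HNF1 targets known from liver, kidney and gut had 7 measured members, 4 of them with positive values (median 0.0807), with FXYD2, a regulator of the sodium pump, at 0.69, the glucose transporter SLC5A2 at -0.58 and FGA, a fibrinogen chain, at 0.30. Only 3 of 15 apical peptidases were measured, too few for a test, with ENPEP at 0.39 and CPM at -0.28 beside DPP4. Medians were 0.26 for 9 plasma proteins of hepatocytes and -0.16 for 9 liver and endoderm transcription factors, where the nuclear receptor NR5A2 had 1.08 (SE 0.36) and SOX9 had -0.42 (SE 0.17). The 14 kidney tubule genes (median -0.12) included the glucose transporter SLC5A1 at 1.02 (SE 0.40) and the sodium channel subunit SCNN1A at -0.72 (SE 0.49), and the 15 cystic kidney and cilium genes (median -0.0404) included BICC1 at 0.65 (SE 0.21), PKD1 at 0.75 (SE 0.46) and NPHP4 at -0.51 (SE 0.41). Of 23 extracellular matrix and mesenchymal genes (median -0.00501), SPP1 passed when adjusted over the list alone (adjusted p 0.0181), and 0 of the 321 members of all lists passed over all probe sets. Medians of the remaining tissue lists were -0.0558 for 18 epithelial junction genes, 0.0189 for 13 conjugation and drug transport genes, 0.0201 for 16 neuronal genes and 0.39 for 6 hematopoietic and endothelial genes, 6 of them positive.

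The lists of general cell state gave medians near 0 with HNF1b: 0.00458 for 15 cholesterol synthesis genes, 0.00134 for 27 genes of ATF4 and the unfolded protein response, -0.0125 for 25 oxidative phosphorylation genes and -0.0223 for 35 proliferation genes. The p53 targets (16 genes) had 0.0112, with the cell cycle inhibitor CDKN1A at -0.43 (SE 0.21). The interferon response (17 genes) had 0.15, the immediate early genes (22) 0.0145, glycolysis and hypoxia (23) -0.0254 and the housekeeping genes (16) -0.0703. MYC and the phosphatase DUSP1 had -0.39 and -0.43 among the immediate early genes. Median, mean and test differed in sign for the cilium, matrix, cholesterol, ATF4, p53 and immediate early lists, and the sign of 10 of the 19 medians changed under quantile normalization or median scaling.

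The same question was asked of HNF1a. TKTL1 rose from 19.4 ± 4.95 (SD, n = 2) to 788 ± 43.6, a log2 change of 3.46 (SE 0.43) and the only one of 15233 probe sets that passed (limma adjusted p 0.00831, higher in both clones). Its second probe set had a change of 1.33 (adjusted p 0.985). PCBD1 measured 2268 ± 109 without and 4030 ± 265 with HNF1a, a log2 change of 0.81 (SE 0.14, adjusted p 0.158), and GLA measured 4579 ± 386 and 7127 ± 68.9, a change of 0.63 (SE 0.11, adjusted p 0.158). NINJ1, an adhesion protein of the plasma membrane, had a change of -1.89 (SE 0.34, adjusted p 0.158). The call of TKTL1 was lost with the clone as a block (adjusted p 0.145), with array weights (0.0604), with no offset (0.476), without the clone 1 uninduced array (0.0656) and without the clone 4 induced array (0.229), over a range of 8.11e-05 to 0.476. The TKTL1 change was 3.46 with the block and with array weights, 3.40 and 3.41 without those arrays, 5.37 with no offset and 2.24 with a larger offset. The block uses the labelled clone pairs, whose deviations from their group means correlated with -0.226 in the HNF1a line. At an unadjusted p under 0.05 there were 712 probe sets (387 higher, 325 lower) where 762 are due by chance. Without the clone 1 induced array, further probe sets passed the adjusted threshold, most of them lower. That fit rested on the clone 4 induced array alone, whose median signal was 355, against 298 on the clone 1 induced array.

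Further genes of smallest p with HNF1a did not pass. DDAH2, of the family that breaks down methylated arginines, had a log2 change of 1.71 (SE 0.33) at one probe set and -0.03 and 0.41 at the others. The matricellular protein CCN3 had -1.28 (SE 0.27) at one probe set and -0.10 at the other, and PSMC3IP, a cofactor of meiotic recombination, 1.12 and -0.24. C11orf68 had 1.24 (SE 0.28), the centrosomal gene CDK5RAP2 1.10 (SE 0.25), and NEFL, the light neurofilament chain, 0.85 (SE 0.19). LGR5 had -0.51 and SPP1 1.35, from a signal of 53.5 ± 2.4 to 226 ± 22.3. DPP4 had 0.28 (SE 0.37) and SERPINA1 -0.47 (SE 0.53), both with an adjusted p of 1.

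**Figure D2:**
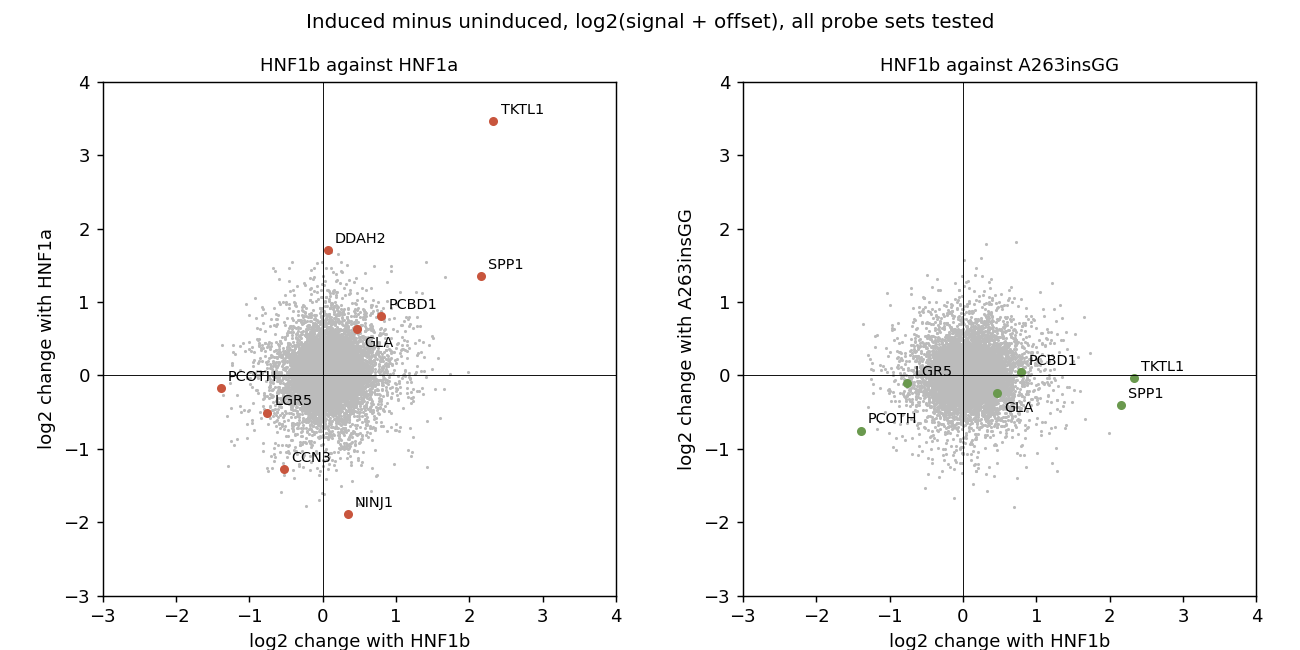
Log2 change with induction of HNF1b (horizontal axis) against that with HNF1a (left panel) or A263insGG (right panel), on the scale of log2(signal + 57.3), for 15233 probe sets, with named genes in colour. TKTL1 lies at 2.33 and 3.46 in the left panel and at 2.33 and -0.04 in the right panel.

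With HNF1a, camera called 0 of 19 lists (adjusted p 0.645 to 0.992, and at least 0.935 with an estimated correlation). The cystic kidney and cilium genes had the smallest p, with 10 of 15 members positive and a median of 0.16, among them BBS1, part of a ciliary transport complex, at 0.76 (SE 0.24) and PKD1, the polycystin of dominant cystic disease, at 1.00 (SE 0.46), with IFT57 at -0.36 (SE 0.24). The HNF1 targets had a median of 0.25 over 7 genes, with FXYD2 at 0.88 and FGA at 0.65, the plasma proteins 0.0798 over 9, and the 3 apical peptidases 0.56, with the aminopeptidase ENPEP at 0.56 (SE 0.23). Of 25 oxidative phosphorylation genes 22 were positive, with a median of 0.063, SDHA at 0.22 and UQCRC1 at 0.23. Among 35 proliferation genes (median -5.9e-05) the mitotic kinase PLK1 had 0.67 (SE 0.16) and passed when adjusted over the list alone (adjusted p 0.0242), while E2F1 had -0.66. CDKN1A had -0.57 in the p53 list (16 genes, median -0.061), SYP -0.95 and ELAVL4 1.12 among the neuronal genes (16, median -0.034), and TM7SF2 1.00 among the cholesterol synthesis genes (15, median 0.00909).

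Medians with HNF1a were -0.17 for the liver and endoderm factors (9 genes), 0.0589 for the kidney tubule genes (14) with SLC12A3 at -0.79, -0.0212 for the epithelial junction genes (18), -0.00197 for the matrix genes (23) with CCN1 at 0.46, and 0.0249 for conjugation and drug transport (13). They were 0.0461 for the ATF4 list (27) with the chaperone PDIA4 at 0.40, 0.0161 for interferon (17), -0.0702 for immediate early genes (22), -0.0143 for glycolysis (23), -0.17 for hematopoietic genes (6) and 0.0408 for housekeeping genes (16). Signs of median, mean and test differed for the liver factor, tubule, junction, matrix, conjugation, cholesterol, proliferation and immediate early lists, and 4 of 19 medians changed sign under another scaling.

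The A263insGG lines were examined for changes with induction of the mutant, and like the other lines they carry any effect of tetracycline itself. KLF4, a zinc finger transcription factor, measured 190 ± 9.26 (SD, n = 2) without and 31.4 ± 4.17 with induction, a log2 change of -1.48 (SE 0.34), and another KLF4 probe set gave 0.05. RGS4, a regulator of G protein signalling, measured 29.8 ± 1.06 and 247 ± 67.1, a change of 1.79 (SE 0.42). The homeobox gene HOXC8 had 1.57 (SE 0.40), the matrix metalloproteinase MMP11 1.32 (SE 0.35) and the B cell surface gene MS4A1 1.81 (SE 0.47). RGS4, HOXC8, MMP11 and MS4A1 read lower in the uninduced A263insGG lines than in the uninduced HNF1b and HNF1a lines. RGS4 measured 29.8 against 169 and 148, and HOXC8 68.6 against 176 and 143. MMP11 measured 52.6 against 213 and 199, and MS4A1 18 against 46.7 and 185. Lower values were found for one probe set of the RNA-binding protein YBX1 (-1.58, others -0.07 and -0.10), the helicase DDX31 (-1.05), the RNA-binding protein DAZAP1 (-0.88), DNASE1L1 (-0.80) and ERG28 (-0.73, another probe set 0.05).

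None of these passed. limma called 0 probe sets for A263insGG, with adjusted p of 1 throughout, and 296 had an unadjusted p under 0.05 (153 higher, 143 lower) where 762 are due by chance. TKTL1, PCBD1, GLA, LGR5 and SPP1 had changes of -0.04, 0.05, -0.25, -0.11 and -0.41 in these lines, and a second probe set of TKTL1 had -0.59.

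Among the lists, camera called 0 of 19 with A263insGG (adjusted p 0.222 to 0.931, and at least 0.758 with an estimated correlation). The 2 of smallest p were the cystic kidney and cilium genes, 11 of 15 positive with a median of 0.14, PKD1 at 0.95 (SE 0.46) and IFT88 at -0.29 (SE 0.20), and the HNF1 targets, 6 of 7 positive with a median of 0.43 and SERPINA1 at 0.88, SLC5A2 at 0.82 and FXYD2 at 0.62. Without the clone 5 induced array 1 list was called, downward, and without the clone 6 induced array 1, upward. Plasma proteins had a median of 0.34, liver and endoderm factors 0.0523, tubule genes -0.0912, junction genes -0.031 with CLDN1 at -0.82, matrix genes 0.0966 with CCN2 at -0.59, and conjugation and transport 0.0482. The 3 apical peptidases had -0.00808, with CPM at -1.09.

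The cell state lists gave 0.000413 for cholesterol synthesis, 0.0163 for ATF4 and the unfolded protein response, 0.00133 for oxidative phosphorylation, -0.024 for proliferation and 0.0185 for p53 targets. Interferon genes had 0.14 with IFIT2 at 1.15, immediate early genes -0.0732 with PHLDA1 at -0.98, glycolysis and hypoxia -0.0583 with EGLN3 at 0.57, neuronal genes -0.0456, hematopoietic genes -0.18 and housekeeping genes -0.0608. Median, mean and test differed in sign for the tubule, ATF4 and p53 lists, and 4 of 19 medians changed sign under another scaling.

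Whether HNF1b and HNF1a act alike was tested as the difference of their induction effects. NINJ1 had a difference of 2.23 (SE 0.48), with 0.34 for HNF1b and -1.89 for HNF1a. SLC1A7, a glutamate transporter, had 2.68 (SE 0.64), with 1.42 and -1.25, although its second probe set gave 0.0072 and 0.14. CDK5RAP2 (-1.49), SSR1 (0.80) and DDAH2 (-1.64) followed. For TKTL1 the difference was -1.14 (SE 0.60). limma called 0 probe sets, all adjusted p near 1, with 466 at an unadjusted p under 0.05, and 1 was called without the HNF1a clone 1 induced array.

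The difference between HNF1b and its mutant was tested likewise. GLA had 0.71 (SE 0.15), with 0.47 for HNF1b and -0.25 for A263insGG. SSR1 had 0.87 (SE 0.20), TKTL1 2.36 (SE 0.60), XRCC4 0.99 (SE 0.26) and ALMS1, a centrosome and basal body gene, -1.09 (SE 0.28), with 0.20 and 0.03 with HNF1b at other ALMS1 probe sets. limma called 0 probe sets and 335 had an unadjusted p under 0.05. Without the intensity trend and robust variance TKTL1 was called (adjusted p 0.0476).

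No gene was called for HNF1b, so the 50 genes of smallest p in each direction were followed in the other lines instead. The 50 higher ones, TKTL1, PCBD1, SPP1 and GLA among them, had positive values for 33 in HNF1a, with a median of 0.0844 and a mean of 0.23 (fry p 0.0355, adjusted p 0.142 over the 4 set tests), and the median was -0.0431 without the HNF1a clone 4 induced array. In A263insGG 31 were positive, with a median of 0.0455 (fry p 0.524). The 50 lower ones, LGR5 and PCOTH among them, had medians of -0.00358 in HNF1a and 0.00765 in A263insGG (fry p 0.0985 and 0.951). Across all probe sets, which are not independent replicates, the changes with HNF1b and HNF1a correlated with r = 0.0731, those with HNF1b and A263insGG with r = 0.0383, and those with HNF1a and A263insGG with r = -0.00499.

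The last comparison set the uninduced lines against each other. YWHAE, a signalling scaffold, measured 1333 ± 134 (SD, n = 2) at one probe set in the HNF1a lines, against 11170 ± 881 in the HNF1b lines and 10530 ± 1250 in the A263insGG lines (limma adjusted p 1.56e-09), and 6221 ± 3180 against 12370 ± 418 and 12320 ± 1230 at another. The proteasome subunit PSMB4 was lower in the HNF1a lines at both probe sets, by -2.03 and -0.66 against A263insGG. All probe sets tested of the centriolar satellite gene PCM1 (5, from -1.01 to -1.67), of BCLAF1 (4, from -1.07 to -1.90), of the cohesin subunit SMC3 (3, from -1.22 to -1.67) and of BZW1 (-1.83 and -1.57) were lower there. For PNN, a spliceosome-associated protein, the values were -1.78, -1.12 and 0.26. The sterol isomerase EBP measured 4543 ± 35.3 against 509.7 ± 36.6 and 499.8 ± 88.2 at one probe set (log2 difference 3.05), while others gave -0.76 and 0.21.

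The moderated F test of limma called 3761 of 15233 probe sets between the 3 uninduced lines, in 2687 genes. HNF1a differed from A263insGG at 1577 higher and 1865 lower probe sets and from HNF1b at 1804 and 2105, whereas HNF1b and A263insGG differed at 0. The 4 HNF1a arrays also stood apart in quality measures, with an actin 3'/5' signal ratio of 1.72 ± 0.159 (SD, n = 4) against 1.35 ± 0.078 (n = 8), a GAPDH ratio of 0.697 ± 0.0254 against 0.804 ± 0.0234, an Alu repeat signal of 86800 ± 15600 against 54100 ± 3820, and poly(A) spike-ins Dap, Phe, Thr and Trp 1.52-fold higher. Median scaling moved the median of all probe sets by -0.101 in HNF1a against A263insGG. Without the HNF1a clone 1 array 2002 probe sets were called, and 2256 without clone 4.

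**Figure D3:**
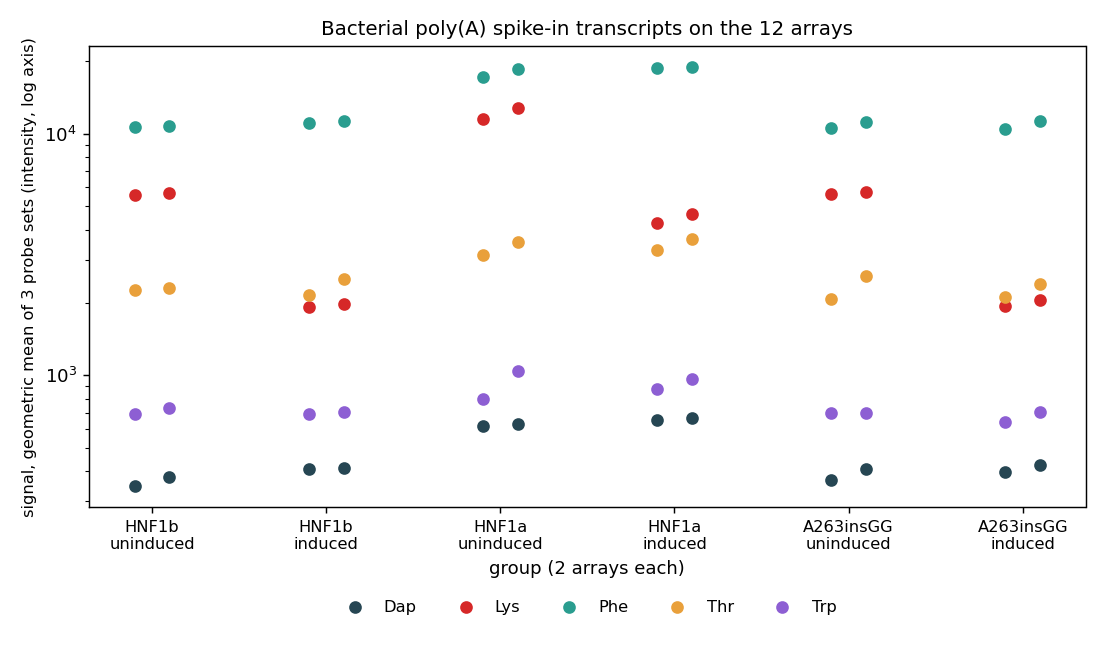
Signal of 5 bacterial poly(A) transcripts added to each sample before cDNA synthesis (geometric mean of 3 probe sets each, intensity on a log axis), for the 2 arrays of each group ordered from low to high. Lys lies between 5574 and 5698 on the uninduced HNF1b arrays and between 1916 and 1967 on the induced ones, and all 5 transcripts lie higher on the HNF1a arrays than on arrays of the same state of the other lines.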

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

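The tests on the Lys transcript, on the other spike-ins and on RNA degradation were chosen after their values had been seen, and the test on probe sets of the same gene was set before its result was seen.

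Lys, a bacterial poly(A) transcript added to the RNA before cDNA synthesis and used in no comparison above, separated induced from uninduced arrays. Its signal was 2.83-fold higher on the uninduced array of a clone and lower with induction in 6 of 6 clones, with a mean log2 shift of -1.5 (two-sided exact permutation p 0.0312 over paired clones, the smallest they can give, and 0.156 adjusted over 10 controls). The 8 other spike-in and hybridization controls had a mean shift of 0.0226 (SD 0.0527), which argues against a scaling or hybridization difference across the array. The shift of Lys had an SD of 0.0597 over the 6 clones, and a second family of Lys probe sets had a shift of -1.41 with an SD of 0.175, which is consistent with different amounts of Lys added to induced and uninduced samples. No biological explanation was tested, since Lys is not a transcript of the cells. The difference ran along with induction in every clone, and whether other handling of the samples that reaches the human genes differed with it was not tested and stays open.

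The spike-ins Dap, Phe, Thr and Trp, also outside the comparisons, were 1.52-fold higher on the 4 HNF1a arrays than on the other 8. The exact permutation p was 0.00202 (two-sided), the smallest this test can give. The permutation exchanged single arrays as if independent, although each clone gave 2 arrays. This p therefore does not hold with clones or lines as the unit. In the HNF1a line the uninduced clones differed from A263insGG at 1577 higher and 1865 lower probe sets and from HNF1b at 1804 and 2105. RNA degradation was taken to raise both 3'/5' ratios. The GAPDH ratio of 0.697 (SD 0.0254) lay below the 0.804 of the other arrays. The actin ratio was higher without overlap, 1.61 to 1.95 on the HNF1a arrays against 1.19 to 1.43 on the others. The 2 ratios disagree, so RNA degradation stays open. The spike-in difference of 0.607 on the log2 scale, beside an SD of 0.0406 over the other 8 arrays, is consistent with another labelling batch for the HNF1a arrays, which cannot be told apart from the line because each line has its own arrays. Sibling probe sets of 2940 genes moved apart 1.37 times as much as the clones alone would give, against 1.04 times for HNF1b. The bootstrap SD of 1.37 was 0.028, but it resampled genes on the same arrays and leaves out the error from 2 clones per line. The ratio of 1.37 lay between the bounds set beforehand, so whether probe sets shifted one by one stays open. Of 381 genes with both siblings called, 21 had opposite signs, and in 731 other genes only 1 sibling was called. A difference between the cells of the lines, such as a lower share of mRNA in the RNA of the HNF1a clones, stays open and was not tested. The Alu repeat signal, between 72112 and 106462 on the HNF1a arrays and between 49455 and 60888 on the others, also follows the line and does not decide between them.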

How the results depend on the processing

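The crossed pairing, the omission of 1 or both HNF1a arrays of highest median signal, the scaling on spike-ins and the average of the wild-type factors were chosen after seeing the data; all other alternatives were planned. Over 48 changes of named genes and 771 combinations with an alternative, 728 kept direction and side of the threshold, 36 lost and 2 gained significance and 5 reversed. Most of the 48 had not passed in the main fit. Only those that had passed could lose significance, so the 36 losses fell on them by definition. TKTL1 with HNF1a kept its call in 10 of 16 alternatives. For the average of the wild-type factors TKTL1 kept it in 19 of 20, PCBD1 in 16, GLA in 11 and LGR5 in 4. The calls of probe sets for HNF1b (0) became 1 without trend and robust variance and 44 with the 2-fold rule, which has no test, and ran from 0 to 1 with an array left out. For HNF1a (1) they became 0 with no offset, with array weights, with the replicate block and without both HNF1a arrays of highest median, 55 with the 2-fold rule, and ran from 0 to 12 with an array left out. With the clones crossed in the block, 2 were called. For A263insGG (0) the 2-fold rule gave 34. The differences (0 and 0) became 419 for HNF1b minus HNF1a and 369 for HNF1b minus A263insGG with the 2-fold rule, 1 for the latter without trend and robust variance, and 0 to 1 for the former with an array left out. Of the uninduced lines (3761), 2399 probe sets were called with 1 probe set per gene, where fewer were tested, 6024 with scaling on 4 spike-ins, 2002 without the HNF1a array of highest median, and 2002 to 3644 with an array left out.

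Lists called for A263insGG (0) ran from 0 to 1 with an array left out, and those for HNF1b and HNF1a were 0 under all 9 alternatives each. For the ranked sets, the median of the higher genes in HNF1a (0.0844) was 0.137 with no offset, where the fry p rose to 0.0985, and with an array left out ran from -0.0431 to 0.291, and in A263insGG from -0.0269 to 0.125. The lower genes in HNF1a came under an unadjusted p of 0.05 with quantile normalization (-0.0604) and the replicate block (-0.00358), and without the HNF1a clone 1 induced (fry p 0.0411) or clone 4 induced array (0.00374), and ran from -0.152 to 0.0303. In A263insGG they were -0.0584 with the replicate block and ran from -0.0892 to 0.0375. SERPINA1 reversed with quantile normalization for HNF1b (-0.04354), and with an array left out ran from -0.29 to 0.45 there and from -1.16 to 0.22 with HNF1a. The average of both wild-type factors (4) gave 1 with median scaling, 2 with no offset, 1 without trend and robust variance, 2 with the replicate block and 1 to 5 with an array left out. The block changed no other call. Where no construction is named, the cause was not tested. A lone array of a group was assumed to vary like the other groups. Without detection calls, the signal over background of single probe sets is not known, and changes of dim ones depend on the offset, as with TKTL1 in HNF1a, at 5.37 without it.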

Other observations

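The tests on the mean of both wild-type factors, on the mutant lines and on the 2-fold overlap were chosen after the values had been seen, and the test over other splits of the arrays was set before its result was seen.

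NEFL, the light neurofilament chain, had positive changes with both wild-type factors at all 3 of its probe sets. They were 0.77, 0.66 and 0.51 with HNF1b, 0.46, 0.85 and 0.66 with HNF1a, and 0.27, 0.09 and 0.02 with A263insGG, none past the limma threshold, and in HNF1a clone 4 the last of them read 4608.7 with and 4738.7 without induction. A DPP4 probe set below the filter read 206.3 and 101.6 in the induced HNF1b clones and 13.1 and 40.7 in the uninduced ones. In HNF1a clone 1 it read 120.4 without and 91.5 with induction, so values of this size also occurred without induction. Another DPP4 probe set below the filter read 29.4 and 23.9 in the induced and 9.8 and 14.3 in the uninduced HNF1b clones. Of the 38 probe sets at least 2-fold higher in both clones with HNF1b and the 34 with HNF1a, 3 were shared, 1 of SPP1 and 2 of TKTL1, where independent lists would share 0.0848, a value that probe sets of one gene do not meet. The A263insGG lines shared none of their 16 higher ones with either, and 1 of their 18 lower ones, of CEACAM1, with HNF1a, where independent lists would share 0.0248. The difference between these overlaps was not tested.

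Averaged over HNF1b and HNF1a, limma called 4 probe sets. TKTL1 rose by 2.89 on the log2 scale (SE 0.30, adjusted p 0.000912), PCBD1 by 0.81 (SE 0.10, adjusted p 0.00427) and GLA by 0.55 (SE 0.08, adjusted p 0.0142), and LGR5 fell by 0.63 (SE 0.10, adjusted p 0.0471), each with the same sign in all 4 clones. The adjusted p ranged over the alternatives from 1.81e-05 to 0.0847 for TKTL1, 0.00188 to 0.239 for PCBD1, 0.00691 to 0.583 for GLA and 0.0223 to 0.408 for LGR5, and the count fell to 1 without the HNF1b clone 1 induced or clone 2 uninduced array and to 2 without the HNF1b clone 2 induced or clone 1 uninduced array. With the clones paired as a replicate block 2 were called, and GLA (change 0.55, adjusted p 0.0945) and LGR5 (change -0.63, adjusted p 0.244) did not pass. LGR5 did not pass without any 1 of the 8 wild-type arrays (0.0793 to 0.408), and GLA without any 1 HNF1b array or the HNF1a clone 4 uninduced array (0.0524 to 0.208). At an unadjusted p under 0.05 there were 717.

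The mutant lines received the same dose of tetracycline. The median ratio of their change to the wild-type one was 0.0246 over the 4 genes (-0.0126 for TKTL1, 0.0618 for PCBD1, 0.168 for LGR5, -0.448 for GLA). The 4 genes were picked for their wild-type change, which by itself favours small ratios. These ratios therefore do not decide whether tetracycline itself had a part in the response, which stays open. The wild-type mean minus the mutant change itself did not pass (adjusted p 0.331 for TKTL1 and GLA, 1 for PCBD1 and LGR5). Among the 35 splits of the 8 wild-type arrays into 4 and 4, 2 called at least the 4 probe sets of the real one, itself included, so this count does not exclude chance. The other is the split of the HNF1a from the HNF1b arrays, the structure of the samples described above, with 6563, which was fitted without the term for the line that all other splits had and so does not measure chance in the same way. The other 33, which mix the lines, called 0. Among these 33 are the 7 others that part all 4 clone pairs, a distinction drawn after the result was seen. Whether the pattern is chance stays open.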
